A study of Homo sapiens with 18 samples.

How the data were processed

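The 18 samples were arrays of human bone marrow mesenchymal stem cells from 3 donors, at the end of passages 1, 4 and 7, with or without 10 ng/ml FGF-2, per the labels. Per the labels' protocols, mononuclear cells were plated in low-glucose DMEM with 10% fetal bovine serum, FGF-2 was added to part of the cultures from the first medium change on day 4, and the plates of both media were subcultured together. The deposited value of each probe set was an intensity, the linear signal that the authors made with MAS5 per the submitters' processing notes. The version of MAS5 and the scaling target are not given in the sources used here. The deposited intensity values were checked to be linear and positive, with a mean, trimmed by 2% at each end, between 500.1 and 500.2 on every array, so that the arrays had been scaled to one mean. Scanner files were not used here. For arrays, their number limits the precision.

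Probe sets were named through GEO's annotation of the array, dated 2016. Of 22277 probe sets, 19070 had 1 gene symbol, 1043 several and 2164 none, and only those with 1 symbol were used; 19058 matched a current gene entry by its number and 0 symbols had to be updated. Genes of X inactivation and of the Y chromosome (31 probe sets) were left out, which left 19039. Each of the 11939 genes was read from 1 probe set, the one with the highest mean log2 value over all arrays, without probe sets of the _x_at class unless a gene had no other; 4304 genes had several probe sets. Values were used as log2(signal + 14), where 14 was the 20th percentile of the positive values. Changes are on the log2(value + pseudocount) scale and understate the folds of genes with low signals. Genes above the 40th percentile of their array on at least 3 arrays were kept, 7946 genes. The rule written beforehand centred arrays whose medians differed by over 0.5, without saying which median. Medians over all probe sets differed by 0.63, with higher low-end signals on the arrays numbered 3, so the arrays were centred on the median of the genes in the fit, which had a range of 0.19. This was chosen after the array medians were seen and before any test, and no centring and centring on all probe sets were added as alternatives.

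The groups were the 6 combinations of medium and passage with 3 arrays each. A limma 3.58.1 fit (R 4.3.3) with 6 group means on all 18 arrays shared 1 estimate of spread (12 residual degrees of freedom, 4.25 prior degrees of freedom, variance trend on). The 9 comparisons were FGF-2 against control at each passage and on average, passage 4 and passage 7 against passage 1 in each medium, and the difference between the media in the change from passage 1 to 7. Tests were two-sided with Benjamini-Hochberg adjustment within each comparison at 0.05. The lists held 611 genes in 24 lists, of which 539 were on the array and 426 were tested, with 10 genes in more than 1 list. They covered the cell cycle, FGF and ERK targets, FGF ligands and receptors, cartilage, bone, fat cells, smooth muscle, collagens and matrix proteins, and matrix proteolysis. TGF-beta and BMP, Wnt and IGF signalling, surface markers, HLA class II, secreted inflammatory factors and interferon response were covered too. Further lists held p53 targets and cell cycle inhibitors (1 list), cholesterol synthesis, glycolysis and hypoxia, ribosomal proteins, and markers of macrophages, lymphoid, erythroid and endothelial cells. Lists with 3 or more tested members entered limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison; an estimated correlation and limma's fry, which tests whether a list's genes move one way without comparing them with other genes, were alternatives. Members past the threshold were counted over all genes and adjusted over the list alone.

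The genes named were the 10 largest rises and 10 largest falls, past the threshold and in the same direction in every same-numbered pair, for the average effect of FGF-2 and passage 7 against 1 in each medium. For the other comparisons they were 5 and 5, with up to 4 members of each list called, by adjusted p, and 15 genes fixed beforehand. The groups, the design, the lists, the naming rule and most alternatives were chosen before the data were examined. The alternatives were pseudocounts of 1 and 56, quantile normalization, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, no variance trend, only the groups compared, the replicate number as a fixed block (10 residual degrees of freedom) or a random one, and each replicate number or array left out.

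That a replicate number marks a donor was inferred from the design of 3 donors and 3 numbers, since the labels do not state it. Deviations from group means were compared between arrays of the same number: 45 of 45 correlations were over 0.1 (0.298 to 0.704, median 0.479), and in 45 of 45 the arrays correlated best with their own number. Blocked values are therefore given beside results whose call they change, and beside counts of changed genes, of a comparison or a list, that they move by over 1.5 times. The procedure was run on simulated data with noise drawn independently for each gene and array. The simulation held no differences between numbers, no ties between passages and no correlation between genes. It therefore does not show how these affect the calls. Of 7946 genes 212 were changed. The FGF-2 comparison at passage 1 recovered 44.6% of changes of 1 and 83% of changes of 2 on the log2 scale. It called 150 genes, 17 of them unchanged. The average comparison recovered 80.4% and 98% and called 204 genes, 16 of them unchanged. In comparisons with no simulated change, passage 7 against 1 in control medium and the interaction, 0 genes were called. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).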

Results

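Gene expression was measured on 18 one-colour Affymetrix arrays of human mesenchymal stem cells, the adherent cells grown from bone marrow that can form cartilage, bone and fat. Cells of 3 donors were expanded in control medium (low-glucose DMEM with 10% fetal bovine serum) or in that medium with 10 ng/ml of the growth factor FGF-2, which was added from the first medium change on day 4. RNA was taken at the end of passages 1, 4 and 7, which gave 6 groups of 3 arrays each. The number in a sample's title, from 1 to 3, was taken as its donor. This was inferred, and the same-numbered arrays deviated from their group means together. Each array had a trimmed mean signal between 500.1 and 500.2 as deposited. Median signals ran from 96.6 to 157, and the number of arrays limits the precision of every value. Values are given as log2 changes of log2(signal + 14) with the standard error of the limma fit (SE, n = 3 arrays per group). P-values are two-sided limma values with Benjamini-Hochberg adjustment over the 7946 genes tested, and they measure the spread between these samples. In the comparison where it is named as risen or fallen, each gene moved the same way in 3 of 3 same-numbered pairs. For the average effect of FGF-2 this check of direction averaged the passages of a number first. The limma fit did not, and took the 18 arrays as independent, with the 3 passages of a number as replicates. Arrays of the same number and medium were tied between passages. The replicate block takes out differences between the numbers, but not ties within a number and medium. The SEs, p-values and gene counts of the average effect, with or without the block, do not allow for these ties. The other comparisons use the same estimate of spread from all 18 arrays. Its residual degrees of freedom count tied arrays as independent, so that their p-values and gene counts carry this limit as well.

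Arrays also differed in ways their groups do not explain. The 6 arrays numbered 3 had a 20th percentile of signal between 20.7 and 26.6, against 9.70 to 13.2 on the other 12. The array of FGF-2 passage 1 replicate 3 had a highest signal of 157161, against 40464 or less elsewhere, and an ACTB 3' to 5' ratio of 2.45, against 1.13 to 1.8. Its median correlation with the other arrays was 0.86, where the other arrays had 0.89 to 0.947. On control passage 1 replicate 1 the poly-A spike dap gave a signal of 3.17, against 5394 or more on the other arrays. The labels give neither a date nor a batch. The first principal component, with 28.7% of the variance, separated the media, the second, with 21.1%, set the arrays numbered 3 apart, and the third, with 13.8%, followed passage.

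The first comparison asked what FGF-2 changed during expansion, as the average of its effects at the 3 passages. HLA-DRA, a chain of the HLA class II proteins that present peptides to T cells, rose by 5.25 ± 0.42. Its mean signal at passage 7 was 4689 ± 3603 with FGF-2 and 42.7 ± 29.6 without (SD, n = 3). CD74, the chaperone of the class II proteins, rose by 3.68 ± 0.2, and HLA-DRB1, read by a probe set that can also bind its paralogs, rose by 5.09 ± 0.34. The chemokine CXCL6 (4.65 ± 0.71), the complement regulator CFI (4.32 ± 0.26), RARRES1 (4.2 ± 0.4) and the transcription factor ETV1 (4.2 ± 0.22) came next. Rises of similar size were in COLEC12 (4.06 ± 0.31), SELENOP (3.78 ± 0.29) and the phosphatase DUSP4 (3.63 ± 0.47). Adjusted p for these 10 genes ran from 8.37e-09 to 0.000225 in limma. The passages counted as replicates in these values, so that the SE of HLA-DRA was 0.42, against 0.73 at passage 4 alone. The largest falls were in filaggrin, FLG (-3.82 ± 0.48), elastin, ELN (-3.76 ± 0.67), and the amino acid transporter SLC38A1 (-3.64 ± 0.54). Next came KRT14 (-3.37 ± 0.5), EFHD1 (-3.31 ± 0.48) and CRIP1 (-3.15 ± 0.38). ACAN, the core protein of the cartilage proteoglycan aggrecan, fell by 3.1 ± 0.49. INHBB (-3.1 ± 0.35), KCND3 (-3.09 ± 0.18) and ITIH5 (-3.06 ± 0.3) fell as well, and adjusted p for the 10 falls ran from 2e-08 to 0.000812 in limma.

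Among genes chosen beforehand for cartilage, bone, fat and growth, SOX9, the transcription factor of cartilage formation, rose by 0.85 ± 0.16 (limma adjusted p 0.00145). The collagen gene COL10A1 of hypertrophic cartilage rose by 1.65 ± 0.45 (limma adjusted p 0.0171), and the fat cell regulator PPARG by 1.31 ± 0.26 (0.00217). COL1A1, the main collagen of these cells, fell by 0.86 ± 0.14 (limma adjusted p 0.000413), and ACTA2, smooth muscle actin, by 0.65 ± 0.19 (0.0294). The inhibitors of FGF signalling DUSP6 (1.22 ± 0.26, limma adjusted p 0.00379) and SPRY2 (0.91 ± 0.23, 0.0116) rose, as did the cell cycle inhibitor CDKN2A (0.6 ± 0.18, 0.0288). CDKN1A, a p53 target, gave -0.48 ± 0.17 with a limma adjusted p of 0.0616, and 0.00796 with the replicate number as a block. FGF2 (-0.32 ± 0.16, limma adjusted p 0.201), its receptor FGFR1 (-0.13 ± 0.13, 0.566, with 1 of 4 other probe sets in the same direction) and the proliferation marker MKI67 (-0.01 ± 0.28, 0.991) did not pass. COL2A1, at a mean signal of 18.2, and RUNX2, at 17.2, lay below the filter on low values and were not tested. The call for ACTA2 was lost when all probe sets of a gene were averaged, and that for CDKN2A when no gene was filtered out or arrays were centred on all probe sets. In all, 1323 of the 7946 genes changed, 16.6%, with 650 higher and 673 lower, and 2339 with the replicate block (1143 higher, 1196 lower). The balance of directions rested on the centring: on all probe sets 439 were higher and 653 lower. Of the 1323 genes, 450 changed by over 2-fold.

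**Figure D1:**
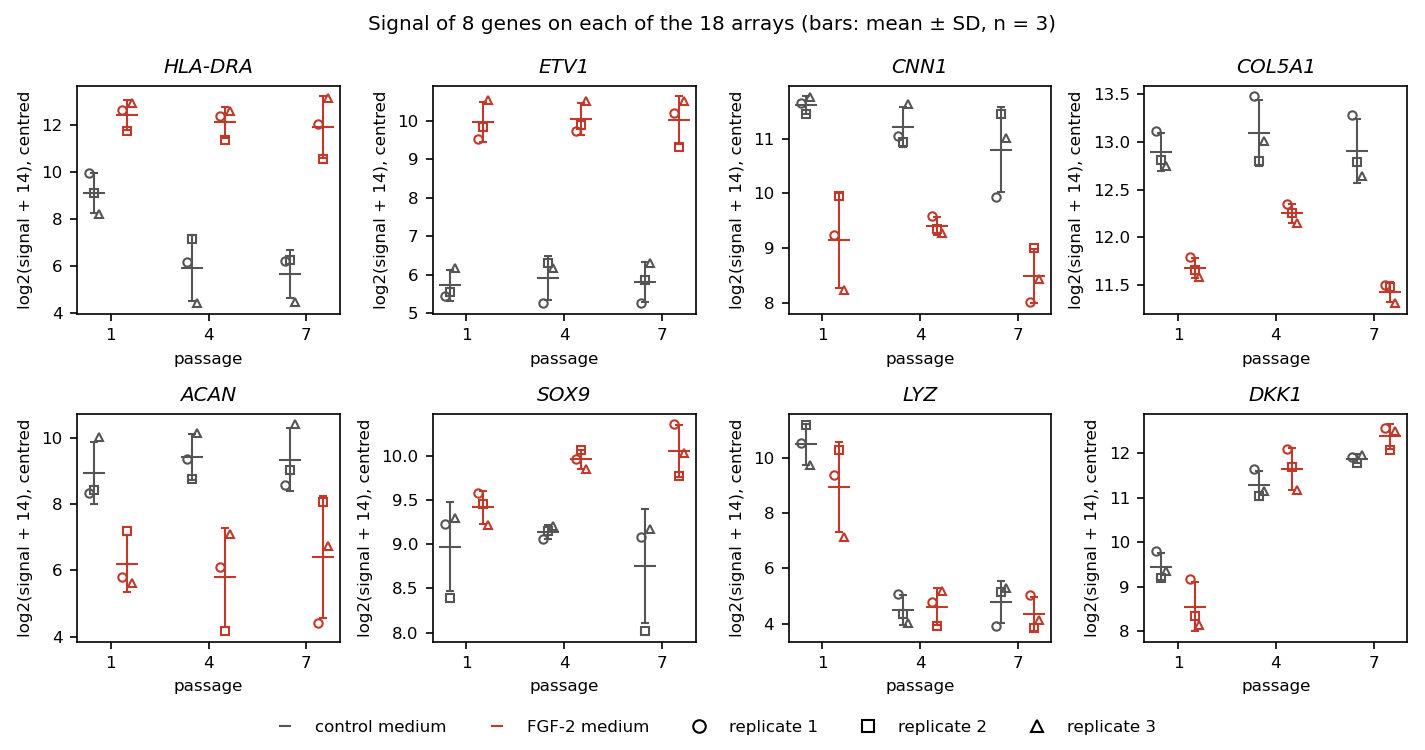
Log2(signal + 14), centred, of HLA-DRA, ETV1, CNN1, COL5A1, ACAN, SOX9, LYZ and DKK1 on each array (points) by passage and medium, with the mean and SD of the 3 arrays per group. HLA-DRA and ETV1 rose by 5.25 and 4.2 with FGF-2 on average over the passages, ACAN fell by 3.1, and LYZ fell by 5.72 from passage 1 to 7 in control medium.

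Of the 24 gene lists fixed beforehand, HLA class II moved most: 7 of 7 members tested rose, over all genes and adjusted over the list alone, with a mean of 3.48 (limma camera adjusted p 5.1e-14, and 0.0361 with an estimated correlation, which was 0.129 with the replicate block). Of its 10 members, HLA-DQA1 (mean signal 29.5), HLA-DQB1 (27) and CIITA (43.2) lay below the filter on low values and were not tested. A gene could pass that filter through FGF-2 arrays alone, which favours members that rise. In smooth muscle and contractile genes 10 of 20 members fell (12 adjusted over the list alone or with the block, mean -0.82, camera adjusted p 2.28e-07, adjusted p = 0.138 with an estimated correlation). These included calponin, CNN1 (-2.2 ± 0.23), the chaperone CRYAB (-2.32 ± 0.32), MYL9 (-1.05 ± 0.15) and LMOD1 (-1.72 ± 0.28). Secreted inflammatory factors rose in 10 of 19 members (11 adjusted over the list alone or with the block, mean 1.36, camera adjusted p 2.28e-07, adjusted p = 0.134 with an estimated correlation). The chemokine CXCL1 rose by 2.84 ± 0.49, CXCL2 by 2.34 ± 0.38 and CXCL3 by 2.37 ± 0.36. Interferon response genes rose in 11 of 24 (12 adjusted over the list alone, 15 and 1 lower with the block, mean 0.7, camera adjusted p 2.28e-07, adjusted p = 0.134 with an estimated correlation). IFI44L rose by 2.58 ± 0.21, BST2 by 1.91 ± 0.31, PSMB9 by 1.44 ± 0.17 and IFI44 by 1.33 ± 0.2. Targets of FGF and ERK signalling rose in 9 of 20 (adjusted over the list alone or with the block 10 rose and 1 fell, mean 0.88, camera adjusted p 9.44e-06, adjusted p = 0.138 with an estimated correlation). These included SPRY1 (2.3 ± 0.26) and PHLDA1 (2.06 ± 0.21).

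Genes of the matrix moved both ways. Collagens and matrix proteins fell in 11 of 33 members and rose in 1 (13 and 3 adjusted over the list alone, 12 and 4 with the block, mean -0.39, camera adjusted p 0.00948, adjusted p = 0.395 with an estimated correlation). COL5A1 changed by -1.18 ± 0.11, MFAP5 by -2.19 ± 0.23 and COL5A2 by -0.75 ± 0.13. The 1 rise was in PCOLCE (0.72 ± 0.14), named after its value was seen. Matrix proteolysis genes rose in 7 of 22 and fell in 1 (9 and 1 adjusted over the list alone or with the block, mean 0.62, camera adjusted p 0.00287, adjusted p = 0.295 with an estimated correlation). These included urokinase, PLAU (2.05 ± 0.18), its receptor PLAUR (0.63 ± 0.11), MMP16 (2.31 ± 0.3) and ADAMTS5 (1.04 ± 0.2). The 1 fall was in ADAMTS2 (-0.55 ± 0.12), also named after its value was seen. FGF ligands, receptors and their proteoglycans fell in 4 of 11 and rose in 1, with the same counts adjusted over the list alone and 5 and 1 with the block (mean -0.38, camera adjusted p 0.0383, adjusted p = 0.134 with an estimated correlation). SDC2 (-1.44 ± 0.13), GPC1 (-1.18 ± 0.21), SDC3 (-0.76 ± 0.18) and, named after its value was seen, FGFR2 (-1.14 ± 0.3) fell, and SDC1 rose by 1.72 ± 0.32. In cell cycle and DNA replication genes only the replication factor CDC6 of 50 members fell (-0.55 ± 0.14), also adjusted over the list alone, and 2 fell with the block (mean -0.3, camera adjusted p 0.0403, adjusted p = 0.814 with an estimated correlation). The plates of both media were subcultured at the same time per the labels' protocols, so that confluence differed between the media. Without replicate 3 the calls for FGF ligands and receptors (camera adjusted p 0.244) and the cell cycle (0.382) were lost, as was that for collagens and matrix proteins without replicate 1 (0.103).

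The other 14 lists tested did not pass in camera for this average. In each parenthesis the first counts are those adjusted over the list alone, the next those with the block, and the last value is the adjusted p of camera. Cartilage genes had 3 members higher and 5 lower of 13 (3 and 6, 4 and 6, mean -0.58, 0.466). Bone genes had 3 higher and 3 lower of 12 (3 and 4, 3 and 5, mean 0.18, median -0.07, with camera pointing down, 0.898) and fat cell genes 2 and 2 of 13 (2 and 4, 2 and 4, mean 0.03, median 0.04, with camera pointing down, 0.771). TGF-beta and BMP signalling had 8 and 4 of 32 (8 and 5, 12 and 5, mean 0.15, 0.208), Wnt signalling 3 and 2 of 19 (4 and 2, 5 and 4, mean 0.24, median -0.01, camera up, 0.794) and the IGF system 1 and 2 of 15 (1 and 4, 3 and 5, mean -0.27, 0.208). Surface markers of these cells had 5 and 7 of 23 (6 and 8, 7 and 10, mean 0.01, median -0.24, camera down, 0.794). Glycolysis and hypoxia had 1 and 3 of 25 (3 and 5, 3 and 8, mean -0.11, 0.208), p53 targets and cell cycle inhibitors 2 and 1 of 15 (2 and 2, 4 and 2, mean 0.1, 0.487), cholesterol synthesis 0 and 0 of 15 (0 and 0, 1 and 2, mean -0.01, 0.981) and ribosomal proteins 0 and 0 of 27 (0 and 0, 0 and 0, mean 0.13, 0.0969). Markers of other cell types gave 0 higher and 1 lower of 9 for macrophages and monocytes (0 and 1, 0 and 1, mean -0.39, 0.208), 1 and 1 of 4 for lymphoid and plasma cells (2 and 1, 2 and 1, mean 0.31, 0.573) and 1 and 0 of 6 for endothelial cells (3 and 0, 2 and 0, mean 0.38, 0.289). The erythroid and megakaryocyte list had under 3 members above the filter and was not tested. When medium was swapped within same-numbered pairs, 12 of 100 swaps, the real one included, gave 9 or more lists in camera. The number of lists called is therefore no evidence by itself of an effect of FGF-2. Swaps that leave most pairs in place keep part of that effect. The count of swaps thus does not show how far the preset correlation of 0.01 makes false calls.

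**Figure D2:**
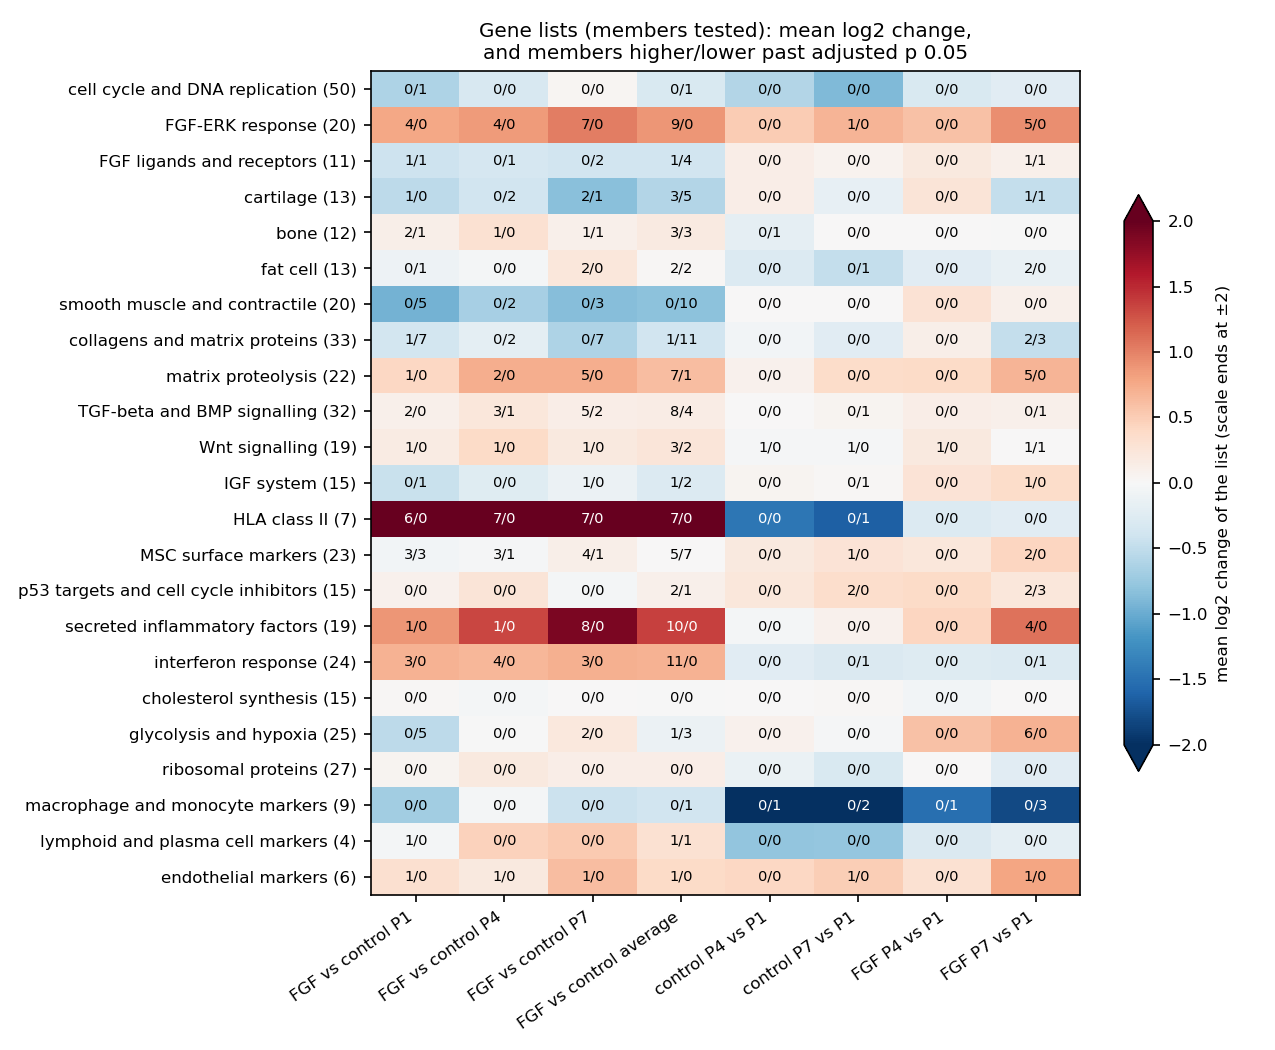
Mean log2 change of the members of 23 gene lists (vertical axis) in 8 comparisons (horizontal axis), as a colour, with the numbers of members higher and lower over all genes tested. HLA class II had a mean of 3.48 with FGF-2 on average and -1.63 from passage 1 to 7 in control medium.

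At passage 1, after the first expansion, ETV1 rose most with FGF-2 (4.25 ± 0.39, limma adjusted p 4.97e-05), followed by COLEC12 (4.17 ± 0.54), CFI (4.09 ± 0.44), HLA-DRB1 (3.83 ± 0.59) and clusterin, CLU (3.67 ± 0.63). The largest falls were in FLG (-3.53 ± 0.83), the cystine transporter SLC7A11 (-3.26 ± 0.54), PSG5 (-3.15 ± 0.68), AMIGO2 (-3.14 ± 0.77) and the serine synthesis enzyme PSAT1 (-3.07 ± 0.62), with limma adjusted p between 0.00241 and 0.0283. Glycolysis and hypoxia genes fell in 5 of 25 members (8 adjusted over the list alone, 9 with the block, mean -0.52, camera adjusted p 1.03e-05, adjusted p = 0.239 with an estimated correlation). These included the glucose transporter SLC2A1 (-1.38 ± 0.32) and the enzymes P4HA2 (-0.93 ± 0.2), PGK1 (-0.85 ± 0.22) and ENO1 (-0.72 ± 0.17). HLA class II rose in 6 of 7 (6 adjusted over the list alone, mean 2.62, camera adjusted p 1.09e-11, adjusted p = 0.0691 with an estimated correlation). CD74 rose by 3.02 ± 0.34. Smooth muscle genes fell in 5 of 20 (6 adjusted over the list alone, mean -0.95, camera adjusted p 1.81e-07, adjusted p = 0.219 with an estimated correlation). CNN1 changed by -2.48 ± 0.4. Collagens and matrix proteins fell in 7 of 33 and rose in 1 (8 and 1 adjusted over the list alone, mean -0.37, camera adjusted p 0.0454, 0.0748 with the block, adjusted p = 0.528 with an estimated correlation). MFAP5 changed by -2.54 ± 0.39, LOX by -1.01 ± 0.2 and LOXL2 by -1.19 ± 0.27. Interferon response (3 of 24 higher, 9 with the block, 7 adjusted over the list alone, camera adjusted p 8.28e-08), FGF and ERK targets (4 of 20, 5 adjusted over the list alone, 0.000305), secreted inflammatory factors (1 of 19, 4 with the block, 2 adjusted over the list alone, 0.00108) and matrix proteolysis (1 of 22, 4 with the block, 2 adjusted over the list alone, 0.0404) were called higher. For these 4 lists the adjusted p = 0.172, 0.265, 0.288 and 0.528 with an estimated correlation. The cell cycle list was called lower with 1 of 50 members, CDC6 at -0.92 ± 0.23, and 0 adjusted over the list alone (mean -0.61, camera adjusted p 0.00266, adjusted p = 0.754 with an estimated correlation). COL1A1 fell by 0.93 ± 0.24 (limma adjusted p 0.0435). ACAN (-2.74 ± 0.86, limma adjusted p 0.0896, 0.0288 with the block) and FGF2 (-0.93 ± 0.27, 0.0714, 0.0315 with the block), each lower in 3 of 3 pairs, passed only with the block. In all 301 genes changed in limma, 140 higher and 161 lower, and 982 with the block (406 higher, 576 lower). Without centring of the arrays the split was 174 higher and 122 lower. Centring on all probe sets moved the median change of all genes from -0.05 to -0.16. The count was 169, 161 or 169 without control passage 1 replicate 1, 2 or 3, and 147 without FGF-2 passage 1 replicate 3.

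At passage 4, HLA-DRA (6.18 ± 0.73) and HLA-DRB1 (5.36 ± 0.59) rose most with FGF-2, with COLEC12 (5.1 ± 0.54), RARRES1 (5.01 ± 0.7) and CXCL6 (4.75 ± 1.24) next, at limma adjusted p from 5.89e-05 to 0.0489. The largest falls were in FLG (-4.57 ± 0.83), KRT14 (-3.85 ± 0.86), EFHD1 (-3.8 ± 0.83), SLC38A1 (-3.66 ± 0.94) and ACAN (-3.64 ± 0.86), at limma adjusted p from 0.00587 to 0.0465. HLA class II rose in 7 of 7 members (7 adjusted over the list alone, mean 3.81, camera adjusted p 3.4e-18, 0.0131 with an estimated correlation and 0.138 with that and the block). Interferon response genes rose in 4 of 24 (5 adjusted over the list alone, 8 with the block, mean 0.67, camera adjusted p 2.17e-05, adjusted p = 0.215 with an estimated correlation). IFI44L rose by 3.07 ± 0.36. FGF and ERK targets rose in 4 of 20 (5 adjusted over the list alone, mean 0.85, camera adjusted p 5.43e-05, adjusted p = 0.215 with an estimated correlation). ETV1 rose by 4.14 ± 0.39 and SPRY1 by 2.53 ± 0.44. Matrix proteolysis rose in 2 of 22 (3 adjusted over the list alone, 6 with the block, mean 0.72, camera adjusted p 0.00233, adjusted p = 0.326 with an estimated correlation), PLAU by 2.3 ± 0.31 and MMP16 by 2.64 ± 0.53. Among secreted inflammatory factors 1 of 19 rose, CXCL6, and 9 adjusted over the list alone or 8 with the block (mean 1.34, camera adjusted p 6.73e-06, adjusted p = 0.192 with an estimated correlation). Smooth muscle genes fell in 2 of 20, CNN1 (-1.81 ± 0.4) and CRYAB (-2.5 ± 0.56), and in 5 adjusted over the list alone or 4 with the block (mean -0.67, camera adjusted p 0.000254, adjusted p = 0.358 with an estimated correlation). FGF ligands and receptors fell in 1 of 11, SDC2 (-1.49 ± 0.23), with the block 2 fell and 1 rose, and adjusted over the list alone 3 and 1 (camera adjusted p 0.0372, adjusted p = 0.192 with an estimated correlation). In the cell cycle list 0 of 50 passed in limma, also adjusted over the list alone and with the block (mean -0.32, camera adjusted p 0.0227, adjusted p = 0.802 with an estimated correlation), and TGF-beta and BMP signalling gave a camera adjusted p of 0.0875, 0.0324 with the block. SOX9 (0.82 ± 0.28, limma adjusted p 0.163, 0.0435 with the block, higher in 3 of 3 pairs), COL10A1 (2.53 ± 0.77, 0.104, 0.00752, higher in 3 of 3) and PPARG (1.18 ± 0.45, 0.229, 0.0453, higher in 2 of 3) passed only with the block. In all 231 genes changed in limma, 122 higher and 109 lower, and 680 with the block (376 higher, 304 lower). The count was 94 or 102 without control passage 4 replicate 1 or 3, and 117 or 112 without FGF-2 passage 4 replicate 1 or 2.

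At passage 7, HLA-DRA (6.25 ± 0.73) and HLA-DRB1 (6.07 ± 0.59) again rose most, followed by CXCL6 (5.17 ± 1.24), interleukin 8, CXCL8 (5.1 ± 0.82), and the decoy receptor IL13RA2 (4.8 ± 0.62), at limma adjusted p from 3.38e-05 to 0.0223. CRIP1 (-4.69 ± 0.66), SLC38A1 (-4.53 ± 0.94), KRT14 (-4.52 ± 0.86), ELN (-4.35 ± 1.15) and the cartilage collagen COL11A1 (-4.27 ± 0.58) fell most, at limma adjusted p from 0.000473 to 0.039. SOX9 rose by 1.29 ± 0.28 (limma adjusted p 0.0118), PPARG by 1.7 ± 0.45 (0.0406) and DUSP6 by 1.76 ± 0.46 (0.0351), and COL1A1 fell by 1.11 ± 0.24 (0.013). ACAN (-2.94 ± 0.86, limma adjusted p 0.0619, 0.0189 with the block), ACTA2 (-1.04 ± 0.34, 0.103, 0.0221), both lower in 3 of 3 pairs, and SPRY2 (1.14 ± 0.4, 0.135, 0.0289), higher in 3 of 3, passed only with the block. HLA class II rose in 7 of 7 members (7 adjusted over the list alone, mean 4.02, camera adjusted p 2.45e-17, 0.0159 with an estimated correlation and 0.153 with that and the block). Secreted inflammatory factors rose in 8 of 19 (8 adjusted over the list alone, mean 1.88, camera adjusted p 1.83e-08, adjusted p = 0.107 with an estimated correlation). The alarmin IL33 rose by 3.63 ± 0.65, CXCL3 by 3.21 ± 0.63 and CXCL2 by 3.02 ± 0.66. FGF and ERK targets rose in 7 of 20 (9 adjusted over the list alone, mean 1.03, camera adjusted p 5.32e-07, adjusted p = 0.148 with an estimated correlation). PHLDA1 rose by 2.35 ± 0.36 and HMGA2 by 1.78 ± 0.39. Matrix proteolysis rose in 5 of 22 (adjusted over the list alone or with the block 7 rose and 1 fell, mean 0.72, camera adjusted p 0.00237, adjusted p = 0.227 with an estimated correlation). ADAMTS5 rose by 1.55 ± 0.34 and PLAU by 2.17 ± 0.31. Collagens and matrix proteins fell in 7 of 33 (9 adjusted over the list alone, 11 with the block, mean -0.61, camera adjusted p 9.51e-05, adjusted p = 0.157 with an estimated correlation). COL5A1 changed by -1.48 ± 0.19 and MFAP5 by -2.28 ± 0.39. Smooth muscle genes fell in 3 of 20, CNN1 (-2.32 ± 0.4), CRYAB (-2.12 ± 0.56) and MYL9 (-0.98 ± 0.27), in 5 adjusted over the list alone and in 6 with the block (mean -0.85, camera adjusted p 1.65e-06, adjusted p = 0.157 with an estimated correlation). Interferon response genes rose in 3 of 24, IFI44L (2.99 ± 0.36), PSMB9 (1.43 ± 0.29) and IFI44 (1.39 ± 0.35), also adjusted over the list alone, and in 7 with the block (mean 0.71, camera adjusted p 2.38e-05, adjusted p = 0.157 with an estimated correlation). In all 393 genes changed in limma, 218 higher and 175 lower, and 956 with the block (528 higher, 428 lower). The count was 257 or 238 without control passage 7 replicate 1 or 3, and 214 or 235 without FGF-2 passage 7 replicate 1 or 3.

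Across the passages 68 genes rose and 60 fell with FGF-2 at all 3, of 563 that changed at any, and 0 changed in opposite directions (174, 151, 1599 and 5 with the block). Passages 1 and 4 shared 78 higher and 67 lower genes, against 2.1 and 2.2 for independent lists, and the log2 changes of all genes correlated at 0.78. Passages 1 and 7 shared 86 and 84 (3.8 and 3.5, correlation 0.67), and passages 4 and 7 shared 92 and 83 (3.3 and 2.4, correlation 0.8). With the block the shared counts were 219 and 206, 224 and 214, and 271 and 205. These correlations are across genes, which are not independent replicates. The comparisons had no array in common but the same replicate numbers.

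The next comparisons asked what passage changed in control medium. Lysozyme, LYZ, an enzyme abundant in macrophages, had a mean signal of 1529 ± 693 at passage 1, 9.42 ± 8.25 at passage 4 and 15.8 ± 13.1 at passage 7 (SD, n = 3), so that the later values lay about the pseudocount of 14. From passage 1 to 4 it fell by 6.01 ± 0.68 (limma adjusted p 0.000939). RNASE1 (-3.75 ± 0.61, 0.0205) and osteopontin, SPP1 (-2.89 ± 0.41, 0.0116), fell as well. The peptidase DPP4 rose by 2.09 ± 0.32 (0.013) and the Wnt inhibitor DKK1 by 1.83 ± 0.28 (0.013). These 5 genes were all that changed in limma. At an unadjusted p under 0.05 there were 259, and 27 passed with the block (13 higher, 14 lower). With centring on all probe sets 1 gene was higher and 3 were lower. The count was 2, 2 or 11 without control passage 1 replicate 1, 2 or 3, and 1 without control passage 4 replicate 1 or 3. Macrophage and monocyte markers were called lower, with 1 of 9 members (7 adjusted over the list alone, 2 with the block) and a mean of -2.17 (camera adjusted p 1.63e-17, 0.0079 with an estimated correlation and 0.126 with that and the block). HLA class II (mean -1.45, camera adjusted p 4.04e-10, 4 of 7 lower adjusted over the list alone) and the cell cycle list (mean -0.59, 7.1e-09, 0 of 50 adjusted over the list alone) were called lower with 0 members past limma over all genes. The adjusted p = 0.0614 and 0.542 with an estimated correlation. FGF and ERK targets (mean 0.51, camera adjusted p 2.01e-06, 0 adjusted over the list alone), surface markers (mean 0.2, 0.0114, 1), p53 targets and cell cycle inhibitors (mean 0.23, 0.00875, 2) and endothelial markers (mean 0.42, 0.00875, 1) were called higher. These too had 0 members over all genes, and 0, 1, 0 and 1 with the block. For these the adjusted p = 0.146, 0.22, 0.22 and 0.076 with an estimated correlation, and the interferon list gave a camera adjusted p of 0.092, 0.0421 with the block.

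From passage 1 to 7 in control medium LYZ fell by 5.72 ± 0.68 (limma adjusted p 0.000622), and HLA-DRA fell by 3.45 ± 0.73 (0.0487). MS4A4A (-3.21 ± 0.56), the scavenger receptor CD163 (-3.19 ± 0.6), RNASE1 (-3.17 ± 0.61), the protease CTSS (-3.07 ± 0.64) and SELENOP (-3.03 ± 0.5) fell as well. So did CFD (-2.2 ± 0.46), IFI44L (-1.95 ± 0.36) and LBR (-1.67 ± 0.25), and limma adjusted p for the 10 falls reached at most 0.0487. KRT18 (3.17 ± 0.63), DPP4 (3.09 ± 0.32), the signalling regulators RGS7 (2.7 ± 0.54) and RGS4 (2.55 ± 0.34) and DKK1 (2.43 ± 0.28) rose. BST1 (2.16 ± 0.33), GATA6 (2.15 ± 0.41), SCG2 (1.91 ± 0.4) and the receptor TEK (1.69 ± 0.31) rose too, with CDKN2A at 1.69 ± 0.31 (limma adjusted p 0.0299). The 10 rises had a limma adjusted p of 0.000313 to 0.0481. GADD45A, a stress gene that p53 induces, rose by 1.1 ± 0.19 (limma adjusted p 0.0142) and cyclin D1, CCND1, by 1.37 ± 0.27 (0.0364). Averaging all probe sets of a gene ended the calls for TEK, RNASE1, CDKN2A and CCND1. Centring on all probe sets ended more calls, as its count of changed genes, given below, was smaller than the number named here. SOX9 (-0.21 ± 0.28, limma adjusted p 0.939), ACAN (0.41 ± 0.86, 0.963) and MKI67 (-0.84 ± 0.49, 0.663) did not pass, and COL10A1 (-2.08 ± 0.77, 0.349, 0.0417 with the block, lower in 3 of 3 pairs) passed only with the block. In all 34 genes changed in limma, 19 higher and 15 lower, and 326 with the block (151 higher, 175 lower). The count was 11 or 9 without control passage 1 replicate 1 or 2, 18, 8 or 21 without control passage 7 replicate 1, 2 or 3, and 22 without FGF-2 passage 4 replicate 2, which enters through the shared spread.

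Macrophage and monocyte markers were lower in 2 of 9 members, LYZ and CD163, in 7 adjusted over the list alone and in 5 with the block (mean -2.08, camera adjusted p 1.32e-09, adjusted p = 0.0866 with an estimated correlation). HLA class II was lower in 1 of 7, HLA-DRA, in 4 adjusted over the list alone and in 3 with the block (mean -1.63, camera adjusted p 2.08e-07, adjusted p = 0.133 with an estimated correlation). The cell cycle list was called lower with 0 of 50 members in limma, 1 adjusted over the list alone and 3 with the block (mean -0.89, camera adjusted p 3.45e-12, adjusted p = 0.402 with an estimated correlation). Ribosomal proteins were called lower with 0 of 27 members, also adjusted over the list alone and with the block (mean -0.3, camera adjusted p 0.000289, adjusted p = 0.636 with an estimated correlation). Called higher were FGF and ERK targets (1 of 20, CCND1, 3 adjusted over the list alone, 2 with the block, mean 0.68, camera adjusted p 8.66e-07), matrix proteolysis (0 of 22, adjusted over the list alone and with the block 2 higher and 1 lower, mean 0.37, 0.0102) and surface markers (1 of 23, BST1, 1 adjusted over the list alone, 3 with the block, mean 0.27, 0.0282). So was the list of p53 targets and cell cycle inhibitors, with GADD45A and the inhibitor CDKN2A (2 of 15, adjusted over the list alone and with the block 3 higher and 2 lower, mean 0.35, camera adjusted p 0.0118). For these lists, in that order, the adjusted p = 0.133, 0.402, 0.355 and 0.319 with an estimated correlation. Endothelial markers were called higher (1 of 6, TEK, 1 adjusted over the list alone, mean 0.49, camera adjusted p 0.0273, 0.0728 with the block, adjusted p = 0.133 with an estimated correlation). The interferon list gave a camera adjusted p of 0.0748, 0.0305 with the block.

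In FGF-2 medium, DKK1 (3.09 ± 0.28, limma adjusted p 4.5e-05), endothelin, EDN1 (2.48 ± 0.4), RGS4 (2.38 ± 0.34) and the mitochondrial carrier SLC25A4 (0.89 ± 0.16, 0.05) rose from passage 1 to 4, and LYZ fell by 4.34 ± 0.68 (0.0208). These 5 genes were all that changed in limma. With an unadjusted p under 0.05 there were 564, and 91 passed with the block (74 higher, 17 lower). With quantile normalization, and with centring on all probe sets, 2 genes were higher and 0 lower. The count was 9 without FGF-2 passage 1 replicate 3, 1, 2 or 3 without FGF-2 passage 4 replicate 1, 2 or 3, and 3 without control passage 7 replicate 3. Glycolysis and hypoxia genes were called higher with 0 of 25 members over all genes, 10 adjusted over the list alone and 3 with the block (mean 0.59, camera adjusted p 1.6e-11, adjusted p = 0.0805 with an estimated correlation). Macrophage markers were called lower with 1 of 9, LYZ, 4 adjusted over the list alone and 2 with the block (mean -1.51, camera adjusted p 9.2e-10, adjusted p = 0.0805 with an estimated correlation). Of the other lists, FGF and ERK targets (mean 0.59, camera adjusted p 0.0002), smooth muscle (mean 0.29, 0.0129), matrix proteolysis (mean 0.39, 0.0318) and p53 targets and cell cycle inhibitors (mean 0.39, 0.0132) were called higher, and the cell cycle (mean -0.31, 0.000337) and interferon lists (mean -0.26, 0.00246) lower. Each had 0 members past limma over all genes, adjusted over the list alone 1, 0, 0, 3, 0 and 0, and with the block 1, 0, 1, 3, 0 and 1. The adjusted p = 0.415, 0.594, 0.594, 0.415, 0.622 and 0.531 with an estimated correlation. Without replicate 2 the cell cycle list pointed the other way (camera adjusted p 0.614).

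From passage 1 to 7 in FGF-2 medium the largest rises were in ANXA10 (4.53 ± 0.68), collagenase, MMP1 (4.21 ± 0.95), NEFM (3.91 ± 0.91), DKK1 (3.82 ± 0.28), RGS4 (3.65 ± 0.34), IL33 (3.52 ± 0.65), EDN1 (3.43 ± 0.4), CXCL8 (3.39 ± 0.82), the integrin ITGA2 (3.31 ± 0.49) and PCOLCE2 (3.25 ± 0.59), at limma adjusted p from 1.96e-06 to 0.0281. LYZ (-4.61 ± 0.68), COL11A1 (-3.58 ± 0.58), MXRA5 (-3.34 ± 0.65), the elastic fibre protein MFAP4 (-3.12 ± 0.57), COLEC12 (-3.06 ± 0.54), AEBP1 (-2.85 ± 0.54), EFNB3 (-2.8 ± 0.65), CCN5 (-2.72 ± 0.64), SERPINB4 (-2.6 ± 0.72) and S1PR1 (-2.57 ± 0.51) fell most, at limma adjusted p from 0.00147 to 0.0486. FGF2 itself rose by 1.71 ± 0.27 (limma adjusted p 0.00234), CDKN2A by 2.14 ± 0.31 (0.00143), CCND1 by 2.54 ± 0.27 (0.00013) and DUSP6 by 1.75 ± 0.46 (0.0367). COL10A1 (-2.51 ± 0.77, limma adjusted p 0.0771, 0.0058 with the block, lower in 3 of 3 pairs) and CDKN1A (0.71 ± 0.29, 0.196, 0.0354, higher in 3 of 3) passed only with the block. SOX9 gave 0.64 ± 0.28 (limma adjusted p 0.229) and ACAN 0.21 ± 0.86 (0.936). In all 378 genes changed in limma, 253 higher and 125 lower, and 1252 with the block (794 higher, 458 lower). The split was 170 higher and 171 lower without centring of the arrays, where the median change of all genes was -0.09 in place of 0.02. The count was 197 or 204 without FGF-2 passage 1 replicate 1 or 3, and 161 or 150 without FGF-2 passage 7 replicate 2 or 3.

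Glycolysis and hypoxia genes rose in 6 of 25 members (11 adjusted over the list alone, 13 with the block, mean 0.7, camera adjusted p 1.12e-07, adjusted p = 0.153 with an estimated correlation). These included ANGPTL4 (3.13 ± 0.53), CA12 (1.13 ± 0.28), PGK1 (0.85 ± 0.22) and P4HA2 (0.82 ± 0.2). FGF and ERK targets rose in 5 of 20 (7 adjusted over the list alone, mean 0.93, camera adjusted p 3.41e-06, adjusted p = 0.153 with an estimated correlation). The cytokine LIF rose by 1.89 ± 0.49. In the list of secreted inflammatory factors 4 of 19 members rose, IL33, CXCL8, LIF and TNFAIP3 (1.46 ± 0.4), the last an intracellular protein and not secreted. Adjusted over the list alone 8 rose and 2 fell, and 8 rose and 1 fell with the block (mean 1.08, camera adjusted p 0.00202, adjusted p = 0.355 with an estimated correlation). Matrix proteolysis rose in 5 of 22 (6 adjusted over the list alone, mean 0.68, camera adjusted p 0.00953, adjusted p = 0.355 with an estimated correlation). ADAMTS1 rose by 1.71 ± 0.22 and tissue plasminogen activator, PLAT, by 2.48 ± 0.61. Collagens and matrix proteins were called lower: LOX (1.34 ± 0.2) and LOXL2 (1.45 ± 0.27) rose and 3 of 33 fell, among them PCOLCE (-1.42 ± 0.24) and MFAP4, with 4 higher and 4 lower adjusted over the list alone and 4 and 7 with the block (mean -0.47, camera adjusted p 0.00454, adjusted p = 0.355 with an estimated correlation). Macrophage markers fell in 3 of 9, LYZ, CYBB (-1.79 ± 0.48) and CD163 (-2.23 ± 0.6), in 8 adjusted over the list alone and in 6 with the block (mean -1.81, camera adjusted p 1.33e-06, adjusted p = 0.153 with an estimated correlation). Surface markers rose in 2 of 23, ITGA2 and BST1 (1.93 ± 0.33), with 7 higher and 3 lower adjusted over the list alone and 8 and 2 with the block (mean 0.43, camera adjusted p 0.0338, adjusted p = 0.355 with an estimated correlation). Endothelial markers rose in 1 of 6, TEK (2.05 ± 0.31), and in 2 adjusted over the list alone (mean 0.79, camera adjusted p 0.0258, 0.0796 with the block, adjusted p = 0.153 with an estimated correlation). The interferon list was called lower with 1 of 24, MX2 (-1.27 ± 0.27), also adjusted over the list alone, and 3 with the block (mean -0.28, camera adjusted p 0.025, adjusted p = 0.563 with an estimated correlation). The ribosomal (mean -0.23, camera adjusted p 0.0146) and cell cycle lists (mean -0.23, 0.0319, 2 of 50 lower with the block) were called lower with 0 members in limma, also adjusted over the list alone, and the adjusted p = 0.822 and 0.828 with an estimated correlation. Both pointed the other way in camera with a number left out, the ribosomal list without replicate 3 (adjusted p 0.103) and the cell cycle list without replicate 2 (0.898).

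The change from passage 1 to 7 was shared in part between the media: 18 genes rose in both (0.6 for independent lists), 5 fell in both (0.2), 0 moved in opposite directions (109, 98 and 0 with the block), and the log2 changes of all genes correlated at 0.57 across genes, which are not independent replicates. Here too the calls shared 1 estimate of spread per gene, so that the lists were not independent. Whether the change from passage 1 to 7 differed between the media was tested as an interaction. CXCL8 gave 5.14 ± 1.16 (limma adjusted p 0.779), IL33 3.33 ± 0.92 (0.839), HLA-DRA 2.92 ± 1.03 (0.998), and ANGPTL4 2.66 ± 0.76 (0.839). In limma 0 genes passed, 336 had an unadjusted p under 0.05 (397 with no change at all), and 0 passed with the block. The camera test called glycolysis and hypoxia higher (mean 0.73, adjusted p 1.63e-11, 3 members adjusted over the list alone), with HLA class II (mean 1.4, 0.00032, 0), cell cycle (mean 0.66, 0.00118, 0) and secreted inflammatory factors (mean 1, 0.0105, 2), each with 0 members over all genes. With an estimated correlation the adjusted p = 0.161, 0.611, 0.911 and 0.911. Collagens and matrix proteins gave a camera adjusted p of 0.13, 0.0447 with the block.

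**Figure D3:**
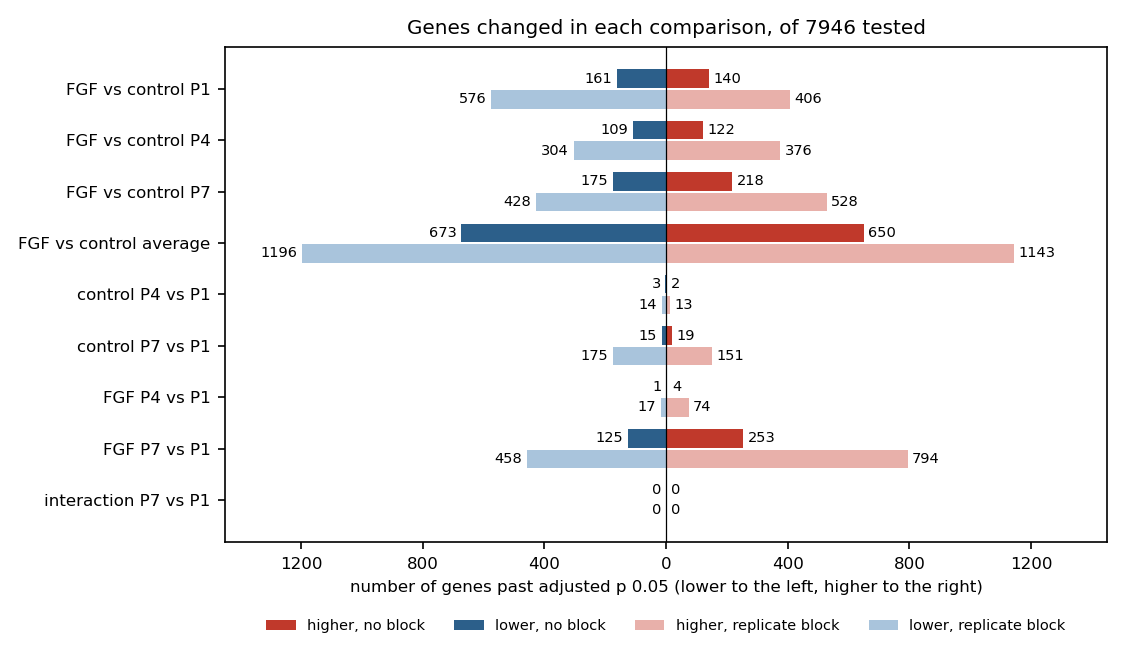
Numbers of genes higher (right) and lower (left) past an adjusted p of 0.05 in limma, of 7946 tested, for the 9 comparisons, without the replicate number (dark) and with it as a block (light). The average effect of FGF-2 gave 1323 genes, passage 7 against 1 gave 34 in control medium and 378 with FGF-2, and the interaction gave 0 in both fits.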

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

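The macrophage and CD74 tests of the HLA class II pattern, the GAPDH and ACTB tests of the glycolysis pattern, the swaps counted for single gene lists, and the minimum of 5 members for the second macrophage list were chosen only after the results were seen. Groups of 3 arrays were not tested for outlying samples.

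Gene lists that changed differently between the media from passage 1 to 7 were singled out by the camera interaction test, at a preset correlation. The mean change with FGF-2 minus that in control medium was 0.66 for cell cycle and DNA replication, 1.4 for HLA class II, 1 for secreted inflammatory factors and 0.73 for glycolysis and hypoxia. With an estimated correlation none of the 4 passed (adjusted p 0.911, 0.611, 0.911 and 0.161), nor in fry (0.856, 0.664, 0.834 and 0.123). In limma 0 genes passed the interaction, with 336 at an unadjusted p under 0.05, where 397 would be found with no change at all. A real count of 0 left the swaps of medium nothing to test, since all 32 had to give 0 or more. The highest of these gave 809 genes, as such swaps turn an effect of FGF-2 into an interaction. A signal also appeared in data that the comparisons left out: of 3207 probe sets with several or no gene symbol, 56 array controls and 21 of genes left out were set aside. Of the other 3130, 1541 passed the filter and 141 of them changed with FGF-2 on average (61 higher, 80 lower; 9.1%).

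For FGF-2 on average, swaps of medium within same-numbered pairs count 9 pairs as independent, but the passages of a number and medium were tied. Between passages 4 and 7 same-numbered arrays correlated across genes at 0.479 to 0.704 within FGF-2 medium and 0.526 to 0.657 within control medium. Across media they did so at 0.33 to 0.381 from control passage 4 to FGF-2 passage 7 and at 0.336 to 0.481 from FGF-2 passage 4 to control passage 7, so that the ranges overlapped slightly. Swaps of medium of whole replicate numbers leave 4 assignments, too few for a share under 0.05: the real one gave 1323 genes and 9 lists, and the highest other 0 and 9. The counts that follow carry this limit. Of 100 swaps within pairs only the real assignment, 1, gave as many as 1323 genes, and the highest other gave 481. Chance was not excluded for the count of lists, since 12 of 100 swaps gave 9 or more and the highest other gave 12. Among all 256 swaps, only 1, the real one, gave a mean shift as large for HLA class II (3.48, highest other 3.01), smooth muscle (-0.82, 0.76), secreted inflammatory factors (1.36, 1.22), interferon response (0.7, 0.59), FGF and ERK targets (0.88, 0.77), matrix proteolysis (0.62, 0.54), collagens and matrix proteins (-0.39, 0.37) and FGF ligands and receptors (-0.38, 0.36), the highest others being sizes. For the cell cycle list 21 of 256 did (-0.3, highest other 0.41), so that chance was not excluded. Among the 14 lists that camera did not call, 1 of 256 did for TGF-beta and BMP signalling (0.15, 0.14), 2 each for cartilage (-0.58, 0.61) and endothelial markers (0.38, 0.41), and 3 each for Wnt signalling (0.24, 0.26) and macrophage markers (-0.39, 0.42). For the other 9 lists 8 to 241 did. Of the comparisons of 3 arrays with 3, each has 10 splits, too few for a share under 0.05. FGF-2 at passages 1, 4 and 7 gave 301, 231 and 393 genes in the real split and 0 in the highest other. Control passage 4 and 7 against 1 gave 5 and 34, with 0 in the highest other, and FGF-2 passage 4 and 7 against 1 gave 5 and 378, with 2 and 1. The splits that parted as many pairs as the real one gave 0 genes. All splits but the real one mix the 2 compared groups, which adds any difference between them to the spread. Low counts were favoured there, so that these zeros are no support for the real counts. Swaps of medium likewise mix the media within groups.

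HLA class II genes were higher with FGF-2, with a mean of 3.48 over the 7 genes tested. Macrophages carried over in the FGF-2 cultures would raise macrophage markers, and the mean of 9 such markers was -0.39, which argues against them. Its SE of 0.13 is taken over the markers, which are not independent replicates, and is not that of the limma fit. Binding between HLA paralogs or donor alleles would not raise CD74, which lies outside that gene family and rose by 3.68 ± 0.2. Such binding therefore does not account for the rise of CD74, a member of the list whose rise was already known. Whether it adds to the values of the HLA genes themselves cannot be told from CD74. The single array of FGF-2 passage 1 replicate 3 was not the source of the list's rise, since the mean was 3.09 without replicate 3. A response of the cells to FGF-2 may explain the rise and stays a hypothesis, found and tested on the same data, and the difference in confluence between the media was not tested.

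Macrophage markers were lower at passage 7 than at passage 1 in control medium, with a list median of -1.85. Genes of that level in general did not fall as much: at most 0.01% of 10000 random lists matched on mean expression had a median as low, the smallest value that can be given. This share does not measure chance, since random genes were drawn independently while the markers were correlated (estimated at 0.314). Of 17 markers on the array 9 passed the filter on low values. LYZ passed it through passage 1, so that a fall from there was favoured. Blood cells carried over from the marrow and lost with passage may explain the drop: LYZ had a signal of 1529 at passage 1, FCER1G 346 and TYROBP 210. A second list of 24 macrophage genes had 6 members tested, of which 3 had a mean signal over 100 at passage 1, and their median was -1.6 (CD53 -1.6, ALOX5AP -1.7, GPNMB 0.18), with 0 past the threshold and 1, ALOX5AP, with the block. The prediction written beforehand was met, but 3 members were judged too few, so that carried-over cells and a change within the stem cells cannot be told apart.

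Glycolysis and hypoxia genes were higher at passage 7 than at passage 1 in FGF-2 medium, with a mean of 0.7. Without the array of FGF-2 passage 1 replicate 3 the mean was 0.6 (camera adjusted p 5.43e-07) and the interaction mean 0.64, so that this array is not the whole source, though 2 members passed in place of 6. The rise started from low values: FGF-2 against control gave a mean of -0.52 at passage 1 and 0.21 at passage 7 (camera adjusted p 0.237). In control medium the mean change from passage 1 to 7 was -0.03. The fall at passage 1, the rises with passage and the interaction all rest on the same 3 FGF-2 passage 1 arrays. Degraded RNA at passage 1 would raise the 3' to 5' ratios there: that of GAPDH was 0.99 to 1.01 at passage 1 and 0.95 to 1.04 at passage 7, higher at passage 1 in 2 of 3 same-numbered pairs, and that of ACTB was 1.17 to 2.45 and 1.36 to 1.46, higher in 1 of 3. The GAPDH ranges overlapped, which was the outcome set for no degradation. The ACTB ratio was raised at passage 1 only on replicate 3, at 2.45. The ratios thus showed no degradation common to the passage 1 arrays. With so few arrays a smaller effect of degradation was not excluded. A difference in confluence between passages or media could give the pattern as well and was not tested.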

How the results depend on the processing

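Centring on all probe sets and no centring were chosen after seeing the data; the other alternatives were planned. Each changed 1 choice. Of 296 recounts of changed genes, 206 were within 1.5 times the value reported. No change of a called gene named in the text reversed; of its recomputed values 13799 kept their side of the threshold, 1111 lost it, 210 gained it, and 116 that passed in neither fit changed sign. The interaction stayed at 0 genes in all settings. With the replicate block, which takes out differences between the numbers, the counts were 982, 680, 956 and 2339 for FGF-2 at passages 1, 4 and 7 and on average, 27 and 326 for control passages 4 and 7 against 1, and 91 and 1252 for FGF-2 passages 4 and 7 against 1. As a random effect it gave 897, 650, 916, 2238, 27, 274, 84 and 1154. Beyond the values given with the results, the block changed no other call of a list named there, and genes kept their calls with it. Over all comparisons 58 values of genes picked by the naming rule passed only with the block, and the results do not print all of these. SLC38A1 with FGF-2 at passage 1, for one, had a limma adjusted p of 0.131, and 0.000935 with the block. With only the groups compared, and thus fewer samples, FGF-2 at passage 1 gave 107, at passage 7 199, control passage 7 against 1 14, and FGF-2 passage 4 and 7 against 1 0 and 66. Centring on all probe sets gave 246 for FGF-2 at passage 7, 8 for control passage 7 against 1, and 2 and 204 for FGF-2 passage 4 and 7 against 1. Control passage 7 against 1 gave 20 with the filter at the 60th percentile, with the mean of all probe sets and with no variance trend. Control passage 4 against 1 gave 9 without a filter and 8 without the trend. FGF-2 passage 4 against 1 gave 2 with a pseudocount of 1 or quantile normalization, and 3 without a filter or with the mean of all probe sets, and passage 7 against 1 gave 245 without a filter, where more genes were tested. Other causes were not tested.

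Of 216 pairs of list and comparison 207 were tested, of which camera called 72, an estimated correlation 4 and fry 42, and the other settings 56 to 74. With a replicate number left out, 3 list calls reversed: the cell cycle list without replicate 2 in FGF-2 passage 4 and passage 7 against 1 (adjusted p 0.614 and 0.898), and ribosomal proteins without replicate 3 in the latter (0.103). The cause was not tested. Over the numbers left out the adjusted p ran from 4.2e-09 to 0.614, 1.32e-06 to 0.898 and 3.75e-05 to 0.103. Another 11, 9 and 16 list calls were lost without replicates 1, 2 and 3. The lists below lost their call at least once, each with its highest adjusted p. For FGF-2 at passage 1 they were cell cycle (0.347), collagens and matrix proteins (0.247) and matrix proteolysis (0.0763), at passage 4 cell cycle (0.518) and FGF ligands and receptors (0.108), and on average those given with the results. For control passage 4 against 1 they were endothelial markers (0.25), FGF and ERK targets (0.102), surface markers (0.15) and p53 targets and cell cycle inhibitors (0.272). For control passage 7 against 1 they were endothelial markers (0.364), matrix proteolysis (0.107), surface markers (0.337) and p53 targets and cell cycle inhibitors (0.126). For FGF-2 passage 4 against 1 they were matrix proteolysis (0.178), p53 targets and cell cycle inhibitors (0.207) and smooth muscle (0.117). For FGF-2 passage 7 against 1 they were collagens and matrix proteins (0.0563), endothelial markers (0.0873), interferon response (0.103), surface markers (0.304) and, without replicate 1, the cell cycle. For the interaction they were cell cycle (0.0502), HLA class II (0.0503) and secreted inflammatory factors (0.131). Leaving out a replicate number or an array gave 6 to 385 genes for FGF-2 at passage 1, 14 to 264 at passage 4, 46 to 427 at passage 7 and 569 to 1394 on average. Control passage 4 and 7 against 1 gave 0 to 19 and 1 to 56, and FGF-2 passage 4 and 7 against 1 gave 0 to 26 and 45 to 389. Fits of equal size differed, with 6, 107 and 116 genes for FGF-2 at passage 1 without replicates 1, 2 and 3, and the cause was not tested. Genes at signals near the pseudocount of 14 were limited by background.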

Other observations

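The themes of the 2 lists on amino acid response and complement were chosen only after PSAT1, SLC7A11, SLC38A1, CFI and CLU were seen to change, and these genes were left out of them; both lists tried are given. PSAT1, SLC7A11 and SLC38A1, which make or import amino acids, were lower with FGF-2, and the hypothesis that other genes of the amino acid response were lower with them was tested. At passage 1 the median of 19 such genes was -1.5, with 13 lower and 0 higher in limma and a negative value in 19. The median was -1.05 at passage 4 (10 lower) and -0.94 at passage 7 (11 lower), and on average 15 of 19 were lower (17 with the block), among them ASNS (-2.65 ± 0.26), TRIB3 (-2.92 ± 0.23) and CHAC1 (-2.14 ± 0.18). DDIT3 (-0.59) and PSPH (-0.93) passed only with the block, and ATF3 (-0.07) and ALDH18A1 (0.06) in neither fit. A lower amino acid response with FGF-2 may link these genes, and a difference in confluence or in the state of the medium was not tested.

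CFI and CLU were higher with FGF-2, and the hypothesis that other complement genes were higher with them was tested. The median of 9 such genes was 0.89 on average over the passages, with 4 higher, C7 (1.79), CFB (1.18), C1R (0.94) and SERPING1 (0.94), and 0 lower, or 1 with the block. C3 gave 0.89 ± 0.43 with a limma adjusted p of 0.179. From passage 1 to 7 with FGF-2, 3 of the 9 rose and 1 fell, or 3 and 3 with the block, with a median of -0.74. For FGF-2 at passages 1, 4 and 7 the medians were 0.63, 0.86 and 0.4, with 1, 0 and 0 of the 9 higher and 0 lower. With the block 4, 3 and 0 were higher and 2, 0 and 0 lower, so that a rise of complement genes as a group stays open.

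That FGF-2 moves genes opposite to the passage change of control cultures was tested by the correlation across genes of the FGF-2 effect at passage 4 with the control change from passage 1 to 7, which share no arrays. The correlations were -0.19, -0.08 and -0.28 for the 3 numbers and -0.2 for the fitted changes. The highest, -0.08, is too near 0 to decide.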
